A study of Mus musculus with 4 samples.

How the data were processed

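The series profiled mouse neural stem cells that overexpressed Six3, 3 h after a change to differentiation medium. Per the labels, 3 libraries were made against FLAG-tagged Six3 and 1 with IgG. Per the labels' protocols, chromatin was digested with a fusion of protein A/G and micrococcal nuclease, DNA was extracted with phenol and chloroform, and libraries were prepared with a ThruPLEX kit. Per the submitters' processing notes, Bowtie2, deepTools and SEACR were used with the mm10 build, without versions, parameters or the order of steps. The name of the deposited table also points to spike-in scaling and to BEDOPS. Other filters, the SEACR mode and threshold, and the rule by which tables were combined are not given in the sources used here.

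The authors deposited a single table of called regions in the 6-column layout of SEACR, without a header. Column 5 is the highest coverage signal in each region, as deposited, and column 4 is the signal summed over the bases of the region, in signal times bp. Both scores are the authors' own and are used to describe, rank or filter regions within the table. Heights were divided by 1.9 and by 0.48, and a region was put in a step set when the result was within 0.001 of a whole number. The sets were recognised after seeing the data. Regions called from separately scaled coverage tracks would give such sets, and signal values of different sets need not be on one scale. Ranked by highest signal, genes and regions are ordered almost wholly by the 1.9-step set. For 2 regions this rule gave no set: one was a multiple of both steps and the other of neither. The first, on chromosome 5, had a highest signal of 45.6. That lay within the range of the 1.9-step set, which reached 205.2, and far above the 0.48-step set, which reached 4.32. It was left unassigned. No column holds the values of a single library, so the planned limma or edgeR test of FLAG against IgG was not run, and the depth per library is unknown. No interval that needs a depth is given.

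Genes came from a RefSeq table of the GRCm38.p6 assembly, which has the coordinates of mm10: 21631 protein-coding genes on chromosomes 1 to 19 and X. The design called for transcription start sites, exons and introns. The table has neither strand nor exons, so windows of 1 kb were placed either side of both ends of each gene, and regions were divided into gene end, gene body and intergenic by their midpoint. Motif density, matching on CpG content and a filter on repeats need a genome sequence and were not run. Of the 334 genes in the 19 fixed lists, 332 matched a symbol.

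The share of regions at gene ends and in each feature was compared with 1000 circular shifts of all regions within each chromosome, by at least 1 Mb, which keep widths and spacing. The overlap of the step sets was tested by shifting the 0.48-step set in the same way. A fold is the observed over the mean shifted share, and its interval is the observed share over the central 95% of the shifted shares. Gene lists were compared with 10000 random lists of the same size, matched on 10 bins of gene length, and p-values were adjusted over the 19 lists by the method of Benjamini and Hochberg. All tests are two-sided. The permutation p-values treat regions or genes as the units and do not measure replicate error. Strongest regions are the top 10% by highest signal; ties at 7.6 made this 215151 regions, 13.6% of the table. All but 2 of these, the regions in neither set, were of the 1.9-step set.

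Genes to name were fixed before the data were examined: Six3; for each list, up to 4 members with the highest signal at their ends and up to 2 with no region; and the nearest protein-coding gene of the 20 regions with the highest signal. Some genes that the rule selects are not reported here. Genes named outside this rule are said to have been chosen after their values were seen. Raised segments were runs of at least 3 bins of 500 kb with more than 1.6 times the autosomal median of summed 1.9-step signal.

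The calculations were tested on simulated data. With 20000 simulated regions on chromosome 19, a planted gene-end fold of 1.1 came back as 1.10 on average and gave p under 0.05 in 46 of 50 runs, against 3 of 50 with no planted fold. For simulated lists of 18 genes among 21631, a planted rise of 35.0 percentage points came back as 34.8 and gave an unadjusted p under 0.05 in 84 of 100 runs, against 2 of 100 with none. A planted segment of 10.0 Mb at a fold of 2.0 was recovered in 5 of 5 runs with 0 false segments. Apart from what was planted, simulated regions were spread evenly along the chromosomes. The rates of false calls therefore need not hold for real coverage that varies along the genome. The simulated lists had a starting share near that of the strongest regions. They do not describe the calls made on adjusted p-values, or the share with any region, which at 94.2% of genes cannot rise that far. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

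Alternatives fixed before the data were examined were windows of 500 bp and 5 kb, the region midpoint, the strongest regions, merging within 200 bp, uniform random placement, covered bases, random lists matched on the number of gene ends within 100 kb, the summed signal, and ranking by width. Shifts of 10 to 50 kb, each step set on its own, regions of equal height in steps, the values outside the raised segments and the gene families were chosen after seeing the data.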

Results

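Binding of Six3 was profiled by CUT&RUN in mouse neural stem cells that overexpressed Six3, a homeobox transcription factor of the developing forebrain and eye. In CUT&RUN an antibody brings a fusion of protein A/G and micrococcal nuclease to a bound protein, and the DNA released by cutting around it is sequenced. Primary neural stem cells, which self-renew in medium with growth factors, had been moved to differentiation medium for 3 h. The series held 3 libraries made against the FLAG tag of Six3 and 1 library made with control immunoglobulin (IgG). The question stated for the study was which genomic regions Six3 binds. The analysed table gave 1578514 regions with a summed and a highest coverage signal. Which of the libraries it combined is not given in the sources used here, and no column belonged to a single library. Signal in the FLAG libraries was therefore not set against the IgG library here, the depth of each library is unknown, and no value below has a replicate error. Whether the authors called the regions against IgG is not given either. Each p-value describes how the regions of this one table lie along the mm10 genome, not the spread between libraries.

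Called regions covered a large part of the genome at low height. After overlapping regions were merged, 1399876 distinct regions remained, and on chromosomes 1 to 19 and X they covered 23.2% of the spanned sequence. The heights fell into 2 sets. In 945652 regions the highest signal was a whole multiple of 1.9 (the 1.9-step set), and in 632860 it was a whole multiple of 0.48 (the 0.48-step set), each within 0.001 of a step. No region overlapped another region of its own set, whereas regions of different sets did overlap. Regions of the 1.9-step set had a median width of 455 bp and a median height of 3 steps, and 343 of them reached 10 steps or more. Regions of the 0.48-step set had a median width of 195 bp, 75.8% of them were 2 steps high, and the tallest reached 9 steps. Which libraries each set came from is not given in the sources used here, so the sets are described by their steps alone.

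**Figure D1:**
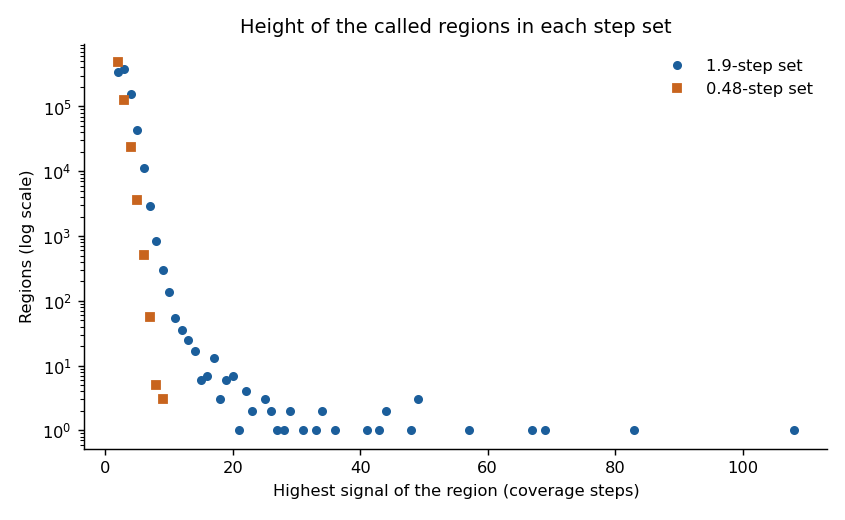
Number of regions (y axis, log scale) by the highest signal of the region in coverage steps (x axis), for the 1.9-step set (circles) and the 0.48-step set (squares). The 0.48-step set ends at 9 steps, and the 1.9-step set extends to 108 steps.

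The ends of protein-coding genes carried slightly more regions than shifted positions did, and this preference lay in the 1.9-step set. Of all regions on chromosomes 1 to 19 and X, 3.82% came within 1 kb of an end of 1 of 21631 protein-coding genes, against 3.61% after circular shifts, a fold of 1.06 (1.04 to 1.07 over 95% of the shifts). For the 1.9-step set the fold was 1.09 (1.07 to 1.11), with a share of 4.12% against 3.77%. For the 0.48-step set it was 1.0 (0.985 to 1.01), with 3.37% both observed and shifted. In the 1.9-step set the fold was 1.04 for regions of 2 steps, 1.1 for 3 steps, 1.14 for 4 steps and 1.21 for 5 steps. For 6 or more steps it was 1.19 (0.969 to 1.44, permutation p = 0.0709). The fold at 5 steps exceeded that at 2 steps by 0.170. Outside the raised segments described below, 1.9-step regions of 4 or more steps had a fold of 1.12 (1.09 to 1.16). The strongest regions over all positions had 1.16. In that comparison shifted regions could still fall inside the segments, and the single heights were not computed outside them. Regions of the 0.48-step set with 4 or more steps had a fold of 1.07 (1.01 to 1.14, permutation p = 0.024).

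By the midpoint of the region, gene bodies held 40.3% of regions against 38.7% after shifting, a fold of 1.04. Intergenic sequence held 56.5% against 58.3%, a fold of 0.969. Gene bodies held more regions than shifted positions did in both sets, with folds of 1.05 in the 1.9-step set and 1.03 in the 0.48-step set. Repeats were not filtered out, so shifted regions could fall where reads cannot be placed and no region can be called. The shorter shifts used at gene ends were not run for gene bodies or intergenic sequence. Whether such sequence accounts for these small folds was therefore not tested. Permutation tests, two-sided, with 1000 circular shifts gave p = 0.001, the smallest they can give, for the gene ends, gene bodies and intergenic sequence over all regions and for the 1.9-step set. The same p was found for the gene-end difference of 0.0916 between the folds of the sets and for that between 5 and 2 steps. At gene ends the 0.48-step set gave a permutation p of 0.982. Strand and exons were not used here, so a gene end is either end of the gene, not only its transcription start.

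**Figure D2:**
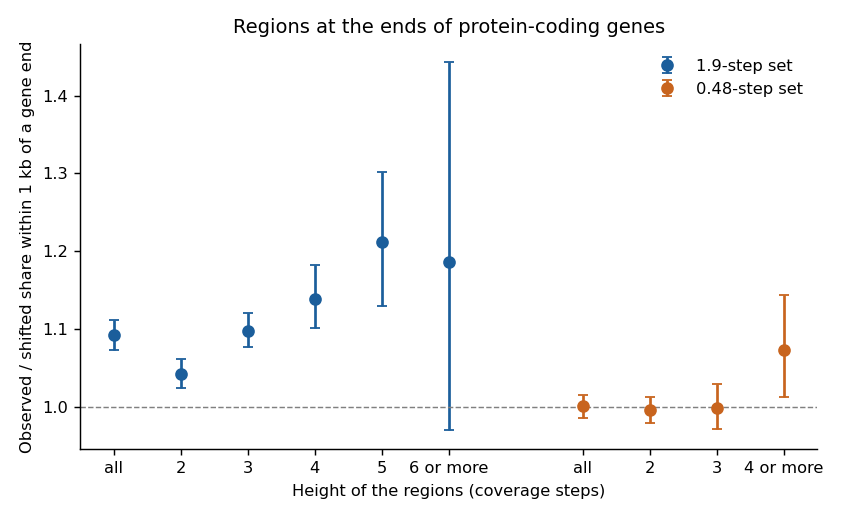
Share of regions within 1 kb of an end of a protein-coding gene, as observed over shifted (y axis), by set and by height in coverage steps (x axis). Points are the fold over the mean of 1000 shifts, and bars take the observed share over the central 95% of the shifts. The fold is 1.09 for all regions of the 1.9-step set and 1.0 for all of the 0.48-step set.

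The 2 sets shared positions only slightly more often than shifted sets did. Of the 0.48-step regions, 27.7% overlapped a 1.9-step region by 1 bp or more, against 26.8% after shifting (fold 1.03, 1.03 to 1.04, permutation p = 0.001, the smallest possible). The fold was 1.07 for 0.48-step regions of 4 or more steps. In the other direction, 17.7% of all 1.9-step regions overlapped a 0.48-step region, against 17.1% after shifting, also a fold of 1.03. Only those of 6 or more steps did so less often than after shifting, at 17.9% against 22.2%, a fold of 0.808 (permutation p = 0.001). With shifts of only 10 to 50 kb, chosen after seeing the data, that fold was 0.958 (0.929 to 0.989, permutation p = 0.006). It was not computed outside the raised segments described below.

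At Six3 itself (chromosome 17, 85613608 to 85626191, mm10) no region stood out in height. The gene held 7 regions, 4 of the 1.9-step set and 3 of the 0.48-step set. The tallest, at 85614739 to 85614960, had a highest signal of 9.5, and a second 1.9-step region at 85620070 to 85620541 had 7.6. A 1.9-step region at 85623587 to 85624051 overlapped a 0.48-step region at 85623396 to 85623782, the only such overlap within the gene. The highest signal inside Six3 stood at percentile 80.9 among 2163 genes of similar length, whose median was 7.6. Within 100 kb of Six3 lay 138 regions, or 649 per Mb, against a median of 665 per Mb around all protein-coding genes (percentile 42.3). The highest signal in that interval, 9.5, stood at percentile 17.4 among genes of similar length. The cells carried added Six3, and whether the regions lay in Six3 exons was not analysed here.

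None of the 19 gene lists fixed before the data were examined stood apart from random lists in the share of members with a region. Over all protein-coding genes 94.2% had a region within 1 kb of an end, so this share had little room to rise. All members had such a region among the Six-family genes and their cofactors (18 of 18), the forebrain and eye patterning factors (20 of 20), the medium spiny neuron markers (15 of 15), the astrocyte genes (16 of 16) and the oligodendrocyte lineage genes (16 of 16). The same held for the Wnt pathway (22 of 22), the Hedgehog pathway (15 of 15), the cell cycle genes (23 of 23), the housekeeping genes (18 of 18), the liver genes (18 of 18), and the endothelial and pericyte genes (15 of 15). Among the neural stem cell and radial glia markers 17 of 18 had one, among the olfactory bulb interneuron factors 19 of 20, and among the pan-neuronal genes 19 of 20. Counts were 17 of 18 for the ependymal and motile cilia genes, 18 of 20 for the Notch pathway, 20 of 21 for the BMP pathway, 17 of 18 for skeletal muscle genes, and 15 of 16 for blood and microglia genes. Listed members without any region at their ends were Hes5 and Dll1, an effector and a ligand of Notch signalling, Tshz1, Sox11, Deup1, Msx1, Tnni2 and P2ry12. All 8 had a region within 5 kb of an end, with a highest signal of 5.7 at Hes5 and Msx1, 13.3 at Dll1 and 7.6 at the others.

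The strongest regions, with a highest signal of 7.6 or more, belonged to the 1.9-step set except for 2 regions in neither set, and 38.9% of all protein-coding genes had one at an end. The Six-family genes and their cofactors had 9 of 18 such members, against a mean share of 40.8% over random lists. Their highest signals were 11.4 at Eya3, a member of the Eya cofactor family, 9.5 at Six5, 9.5 at the corepressor gene Tle2 and 7.6 at Tle5. Six3 reached 3.8 within 1 kb of its ends and 9.5 within 5 kb. Of the forebrain and eye patterning factors 7 of 20 had a strongest region, led by Rax, an eye field homeobox gene, with 9.5, and by Vax2 and Emx2 with 7.6 each. Of the olfactory bulb interneuron factors 9 of 20 had one, with 11.4 at Th (tyrosine hydroxylase), 11.4 at Gad1, an enzyme of GABA synthesis, and 9.5 at Gsx1. Among the medium spiny neuron markers 6 of 15 had one, with 9.5 at Penk and 7.6 at Adora2a and Drd2. Of the neural stem cell markers 6 of 18 had one, with 7.6 at Nr2e1, Id1, Vim and Notch1.

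Strongest regions marked 7 of 18 liver genes, led by Cyp7a1, an enzyme of bile acid synthesis, with 11.4, and 7 of 18 skeletal muscle genes, led by Cacna1s and Pvalb with 9.5 each. They marked 6 of 18 housekeeping genes, with 11.4 at Eef1a1, and 4 of 16 blood and microglia genes, with 11.4 at Spi1. Endothelial and pericyte genes had the highest share, 10 of 15 or 66.7%, against 39.8% over random lists, with 11.4 at Flt1 and at Kcnj8. That list gave an unadjusted permutation p of 0.0371 and an adjusted p of 0.705. Without genes in the raised segments, which are described below and were defined after seeing the data, the share was 64.3% with an unadjusted permutation p of 0.0532. Astrocyte genes had the lowest share, 3 of 16 or 18.8%, against 39.7% (permutation p = 0.125, adjusted p = 1.0). The remaining shares were 8 of 20 for pan-neuronal genes (9.5 at Tubb3), 6 of 18 for ependymal genes (9.5 at Mcidas) and 6 of 16 for oligodendrocyte genes (9.5 at Sox10). They were 8 of 22 for the Wnt pathway (9.5 at Axin2), 6 of 15 for the Hedgehog pathway (11.4 at Sufu), 8 of 20 for the Notch pathway (11.4 at Nrarp), 6 of 21 for the BMP pathway (9.5 at Msx2), and 12 of 23 for the cell cycle genes (15.2 at Cdk6). The median highest signal was 5.7 in 16 of the lists, 6.65 in the Six-family genes and their cofactors, and 7.6 in the cell cycle and the endothelial and pericyte genes. By summed signal the Six-family genes and their cofactors had the lowest median of the 19 lists, 2291.9 against 3449.7 over random lists (permutation p = 0.109, adjusted p = 0.821).

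In two-sided permutation tests with 10000 random lists matched on gene length, no list passed an adjusted p of 0.05, adjusted over the list alone, that is over the 19 lists. For the share with any region and for the median highest signal, 0 lists had an unadjusted p under 0.05, and for the strongest regions 1 had. The median highest signal moved in coarse steps and could hardly give a call. At 7.6, the upper end of the random range, the permutation p was 0.182 for cell cycle genes and 0.226 for endothelial and pericyte genes. Genes of the 19 lists inside the raised segments described below included Gsx1, Flt1, Sox10, Pvalb, Wnt1 and Mfng.

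**Figure D3:**
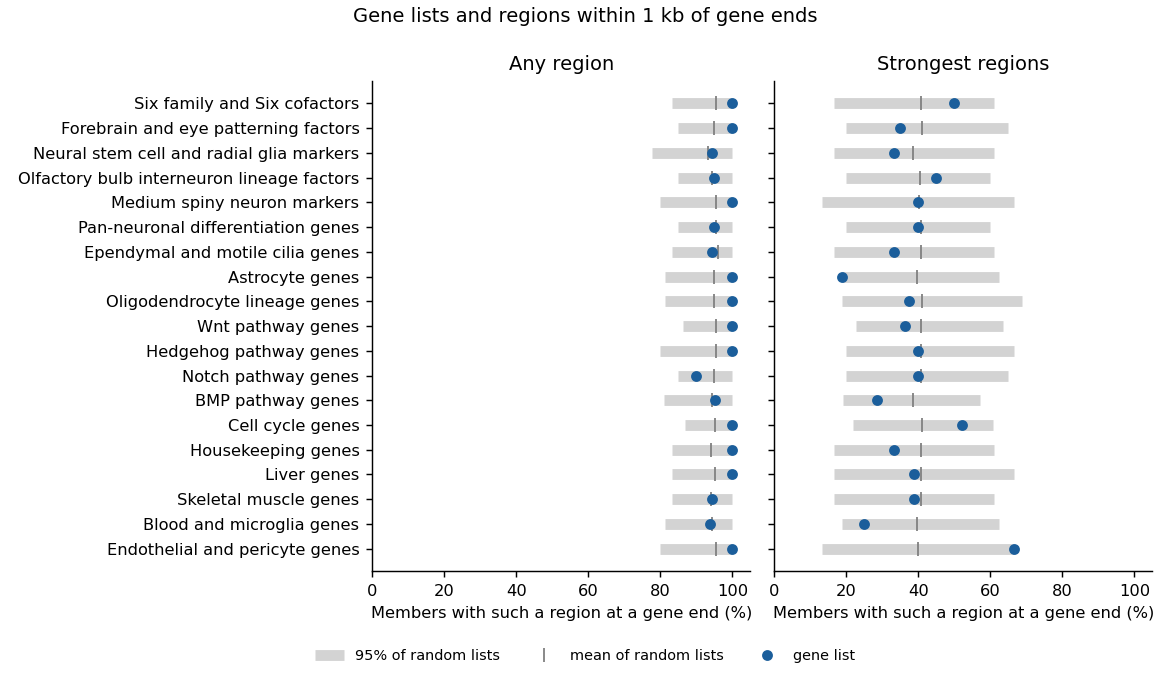
Percentage of members of each gene list with a region within 1 kb of a gene end (x axes), for any region (left) and for the strongest regions, highest signal 7.6 or more (right). Dots are the lists, ticks the mean and bars the central 95% of 10000 length-matched random lists; endothelial and pericyte genes are highest on the right, at 66.7%.

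The 20 tallest regions lay both inside and outside genes. The region with the highest signal, 10841.2, spanned 4017 bp at 19415687 to 19419703 on chromosome 14, outside genes and 114 kb from the nearest protein-coding gene, Gm2244. Its signal was a whole multiple of neither step. The other 19 of the 20 belonged to the 1.9-step set. The tallest of these was 77 bp wide and lay inside Acacb, an acetyl-CoA carboxylase gene (chromosome 5, 114173100 to 114173176), with a signal of 205.2. Others lay inside Prkdc (131.1), which encodes the catalytic subunit of DNA-dependent protein kinase, Dpp9 (127.3), Ybx3 (108.3), Zfp949 (93.1), Auts2 (83.6), AW554918 (68.4), Plxdc2 (64.6) and Sepsecs (58.9). Outside genes, the nearest protein-coding genes were Gm8882 (157.7), Pla2r1 (93.1), Bambi (93.1), Rorb (91.2), Unc5d (83.6), Sulf1 (81.7), Olfr854 (77.9), Samd9l (64.6), Ankle1 (62.7) and Bcl11a (55.1), at distances of 8.03 to 926 kb. Of the 20 regions, 9 lay inside a gene, 0 had their midpoint within 1 kb of a gene end, and 0 were overlapped by a 0.48-step region. The 20 widest regions shared 0 regions with these 20, and all of them lay in the raised segments of chromosomes 5 and 15.

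Among chromosomes 1 to 19 and X, the density of the 1.9-step set was highest on chromosome 15 and lowest on chromosome X. Chromosome 15 had 479 regions of the 1.9-step set per Mb, 1.27 times the autosomal median, against 0.978 times for the 0.48-step set. The other 18 autosomes lay between 0.922 and 1.07 times the median for the 1.9-step set and between 0.950 and 1.04 times for the 0.48-step set. Chromosome X lay at 0.470 times the autosomal median in the 1.9-step set and at 0.718 times in the 0.48-step set. In bins of 500 kb, runs of at least 3 bins with more than 1.6 times the autosomal median of summed 1.9-step signal formed 12 segments with a total of 60 Mb and 811 protein-coding genes. These segments, defined after seeing the data, lay on chromosomes 5, 10 and 15.

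At the end of chromosome 5, between 144500001 and 152000000, the median relative 1.9-step signal was 3.92, and the median relative number of regions was 1.34 for the 1.9-step set and 0.111 for the 0.48-step set. The bin of Brca2, a DNA repair gene in that segment chosen after its values were seen, had a relative 1.9-step signal of 4.64, but the number of regions was below the autosomal median in both sets, with 135 of the 1.9-step set (relative number 0.711) and 3 of the 0.48-step set. On chromosome 15 the segment from 54500001 to 65000000 had a median relative signal of 2.41, a maximum of 5.40 and a median relative number of 0.48-step regions of 0.865. The bin of the proto-oncogene Myc, also chosen after its values were seen, had 5.18 there, with a relative number of regions of 1.86 for the 1.9-step set and 0.317 for the 0.48-step set. The segments on chromosome 10, from 82000001 to 87000000 and from 87500001 to 92000000, had medians of 1.89 and 1.81. There the relative number of 0.48-step regions was 0.956 and 0.937. The bin of Six3 had a relative 1.9-step signal of 1.07 and a relative number of 0.48-step regions of 1.0.

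**Figure D4:**
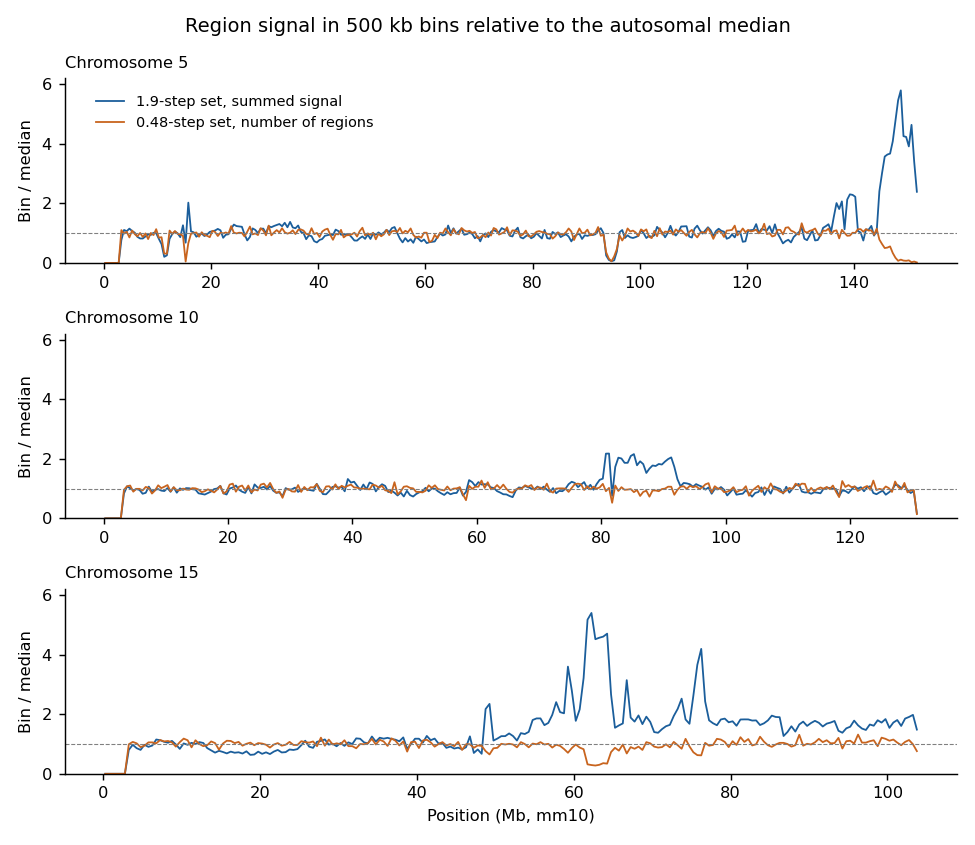
Signal along chromosomes 5, 10 and 15 in 500 kb bins (x axis, position in Mb), relative to the autosomal median (y axis). Blue is the summed signal of the 1.9-step set and orange the number of regions of the 0.48-step set; the last segment of chromosome 5 has a median of 3.92 in blue and 0.111 in orange.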

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

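A single region carried a signal far above the range of both step sets. Its signal was a whole multiple of neither step, so it entered none of the comparisons made by set. It lay on chromosome 14 at 19415687 to 19419703, outside genes. Its highest signal was 10841.2, against a highest value of 205.2 in the 1.9-step set and 4.32 in the 0.48-step set. The level of the IgG library at this position was not analysed here, and no explanation was tested.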

How the results depend on the processing

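Of 71 alternative values of the results that answer a comparison, 56 kept their direction and their side of the threshold, or stayed within 1.5 times the main count. No paired analysis was possible because the regions carry no replicate and IgG has 1 library. The gene-end preference of all regions, 1.06, kept its direction and p under 0.05 with every window, placement and merging tried, between 1.01 with shifts of 10 to 50 kb and 1.16 in the strongest regions; taken over the 0.48-step set alone it was 1.0 and lost the call. For the 1.9-step set it lost the call only at 6 or more steps, at 1.19 (permutation p = 0.0709). The 0.48-step set, at 1.0, fell below 1 without passing the threshold with the 500 bp window (0.988), the midpoint (0.994, in the division by feature too), uniform placement (0.999), shifts of 10 to 50 kb (0.989), outside the segments (0.985), and at 2 steps (0.996) and 3 steps (0.999). It passed the threshold with the 5 kb window (1.01) and at 4 or more steps (1.07). For the values outside the segments, shifted regions could still fall inside them. Keeping the strongest regions left 215151 regions. Ranking by width shared 0 of the 20 tallest regions. The raised segments numbered 5 above 2 times the median, on chromosomes 5 and 15 but not 10, with 18.5 Mb against 60 Mb, and 9 to 13 in the other settings. The number of lists past an adjusted p of 0.05 was 0 in every setting run. This is no support where the permutation p was 1.0 for every list: with the 5 kb window all shares were 100%, and the median signal of the 0.48-step set was 0.96 in every list. Both settings are counted among the 56. In the strongest regions 1 list had an unadjusted p under 0.05. Of 83 named genes, 26 had another highest signal with the 5 kb window. The causes of these changes were not tested. Not run were the FLAG against IgG test with its alternatives, motif density with its alternatives, and matching on CpG content. The depth of the libraries is unknown, and what it limits was not tested.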

Other observations

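Gene families were chosen after seeing the values of the lists. Vomeronasal receptor genes, which detect pheromones, had regions at their ends less often than length-matched genes: 74.9% of 355 genes had any region against 90.1%, 65.1% had a 1.9-step region against 81.1%, and 45.6% had a 0.48-step region against 60.1%. A strongest region marked 21.1% of them against 30.4%. Odorant receptor genes had any region more often, 90.8% of 1110 genes against 81.9% of other genes of the same lengths, with 79.2% against 71.4% for the 1.9-step set and 59.4% against 52.2% for the 0.48-step set. Solute carrier genes had any region in 98.5% of 389 genes against 95.6% (permutation p = 0.00699, adjusted p = 0.0315), but did not pass the threshold for the 1.9-step set (92.0%, adjusted p = 0.424), the 0.48-step set (72.5% against 67.3%, adjusted p = 0.0858) or the strongest regions (40.6% against 41.2%, adjusted p = 0.987). The adjusted p over 36 comparisons of 9 families was 0.00514 for each of the receptor values above, except that the odorant receptor genes carried a strongest region in 22.0% against 24.6% (adjusted p = 0.0874). These tests used 1000 random lists and treated neighbouring genes as independent, although receptor genes lie in clusters. How well reads can be placed in these genes was not tested.

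Mitochondrial ribosomal protein genes had a strongest region in 52.6% of 78 genes against 39.5% (unadjusted p = 0.027, adjusted p = 0.0858), and cytosolic ribosomal protein genes in 47.0% of 100 against 37.4% (adjusted p = 0.113). Zinc finger genes, keratin genes, homeobox cluster genes and protocadherin genes had strongest regions in 41.0%, 41.5%, 38.5% and 34.8%, with adjusted p-values of 1.0, 0.993, 0.993 and 0.619. On chromosome Y the 0.48-step set had 98 regions, 91 of them below 90 Mb, and the 1.9-step set 42, 17 of them below 90 Mb. In mitochondrial DNA each set had 1 region, and both covered positions 9769 to 10037.

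The tests of tall regions, of extra DNA copies, and of all 3 explanations of the gene-end preference were chosen after the results were seen. The raised 1.9-step signal on chromosomes 5, 10 and 15 was not made by a few very tall regions, since the median relative signal of the segment bins was 1.88 with all regions and 1.61 without those of 5 steps or more. The rise was not confined to the surroundings of genes. More than 5 kb from any gene, the segments held 1.66 times as many 1.9-step regions per Mb as other autosomal sequence, and 1.52 times as many nearer to genes. The segments had been selected for high 1.9-step signal, so ratios above 1 were likely in both places. Gene-rich open chromatin is therefore not excluded. Extra DNA copies of the segments may account for the pattern as a hypothesis. In the segments 29.9% of the 0.48-step regions had 3 steps or more, against 24.4% elsewhere on the autosomes (24.5 to 28.4% after shifts, permutation p = 0.001, the smallest possible). This cannot be told apart from other causes here, because the number of 0.48-step regions did not move alike in the segments. Their median relative numbers ran from 0.111 at the end of chromosome 5 to 1.13 on chromosome 15. The hypothesis called for 0.48-step regions at least as dense as elsewhere, but their density over all segments was 0.880 times that. In the bin of Myc their relative number was 0.317. The number of called regions need not follow coverage, so it cannot decide on extra copies. In the bin of Brca2 the relative 1.9-step signal was 4.64, with a relative number of 1.9-step regions of 0.711. In 11 of the 12 segments the 0.48-step regions were taller, by the share of 3 steps or more, than elsewhere on the autosomes.

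The gene-end preference of the 1.9-step set over the 0.48-step set remained at equal numbers of steps. The difference of the folds was 0.0458 among regions of 2 steps and 0.0993 among regions of 3 steps, both above the shifted ranges. This does not exclude height or the calling threshold, because a step need not mean the same in both sets. The least summed signal, in steps times bp, was 460 in the 1.9-step set and 50 in the 0.48-step set. The raised segments alone did not account for the difference, which was 0.0819 outside them, with folds of 1.07 and 0.985. The regions outside were shifted over the whole chromosome, so shifted regions could still fall inside the segments. These 2 folds are therefore not directly comparable with those over all regions. Coverage that varies over more than 50 kb could account for much of the gene-end excess of the 1.9-step set. Shifts of 10 to 50 kb lowered its fold from 1.09 to 1.03, with an interval of 1.02 to 1.04 that stayed above 1. Cutting at open chromatin irrespective of Six3 stays open, because the IgG signal was not analysed here on its own.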
